A study of Homo sapiens with 8 samples.

How the data were processed

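The libraries came from the human glioblastoma cell line LN229, grown on multiwell plates and treated for 48 h with bortezomib (7.5 nM) plus panobinostat (15 nM) or with DMSO, per the labels' protocols. There were 4 samples of each kind. The labels disagree on details: a sample label calls the controls untreated while the treatment protocol names DMSO, and the extraction text speaks of brain tissue while all samples are labelled as the cell line. RNA was extracted with a phenol reagent and a kit, and libraries followed the sequencer maker's standard protocol, per the labels' protocols. Whether the kit kept strand is not given in the sources used here.

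The authors deposited 1 table of FPKM values with 58735 genes and 1 column per sample, per the file headers. The submitters' processing notes name the aligner Bowtie 0.12.2 and the builds mm8 and GRCh37, without saying what each was used for. In the deposited table all 58735 gene identifiers and all 58735 sets of coordinates equal those of GENCODE release 29 on GRCh38, and 58708 symbols are the same. All 58735 gene lengths equal the summed length of the merged exons. Coordinates printed here are therefore GRCh38, as the table gives them. The counting tool is not given in the sources used here.

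FPKM multiplied by gene length was a whole multiple of 1 step in each column (100% of nonzero values, within 0.02 of a whole number), so the reads behind each value could be read back. Totals ran from 15189251 to 17324292 reads. The number of reads that the authors' scaling divided by was 0.954 to 1.003 times this total in the combination samples and 1.026 to 1.041 times in DMSO. The deposited values of the combination samples therefore stand higher, relative to DMSO, than library totals alone would give. A gene of 1 kb with 3 reads stands at 0.172 to 0.197 FPKM, which limits what low values can show. These floors cover counting error only.

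The design written before the data were examined named a count test if the table held counts, and otherwise limma on log2(value + 1). Since the deposited unit is FPKM, the latter was used: limma 3.58.1 in R 4.3.3, a linear model with the group as the only term, moderated with a mean-variance trend, on log2(FPKM + 1) over the 13296 genes with a mean of at least 1 FPKM over all 8 samples. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 2-fold counts add a filter on the fitted change and are no test against 2-fold. Gene lists (34) had been written beforehand from textbook knowledge, 8 of them markers of cell types. Lists with at least 3 tested genes were tested with camera of limma at the preset correlation of 0.01, two-sided and adjusted over all lists. The replicate numbers in the titles were not used for pairing in the main model.

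Genes named in the text follow a rule also written beforehand. It takes the 8 largest increases and the 8 largest decreases among called genes whose groups do not overlap, then from each list the called genes with the smallest p in each direction (up to 2 each way, or the smallest p if none passed), and last a fixed set of stress, apoptosis, drug target, repair and reference genes. Not all of these are printed, and some results are not reported here. Library measures were compared with an exact permutation test, two-sided.

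The model was tested on simulated reads for the same libraries, with 200 genes changed by known folds. Of 50 genes changed 2-fold, 82% were recovered in the right direction, of 50 changed 4-fold 88%, of 50 changed 1.5-fold 78% and of 50 changed 1.25-fold 60%, with 12461 genes in the step. Of each 50 changed genes, 44 or 46 passed the filter on low values, so part of the loss came from the filter. There were 7 calls among 12279 unchanged genes. In a simulation that raised the proteasome list alone, camera called that list and 0 of the others. Simulated genes were independent, had the spread of the DMSO samples, and nearly all were unchanged. In the real data most genes were called and list members were correlated, so these error counts need not hold there.

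The alternatives were other scalings (library totals, median-of-ratios, upper-quartile and TMM factors, quantile normalization), other filters, other pseudocounts, the replicate number as a block, and leaving out each sample. For lists they also included an estimated correlation and the fry test. Chosen after seeing the data were voom of limma on the recovered reads, scaling by the reads of nuclear genes, and some of these scalings for the lists. Exon overlaps between genes were computed from GENCODE 29. Among the genes named, over 20% of exon length lay under exons of other genes, on either strand, for BCL2L1 (43.0%), DDIT3 (39.6%), HSPA1B (36.5%), IFITM1 (32.5%), RPS2 (25.6%), RAD54L (25.1%), BCL2L2 (24.3%), ATF5 (23.7%), NDUFS3 (22.4%), SQSTM1 (22.0%), IFITM3 (21.3%), NFE2L2 (20.9%), IL6 (20.7%), PSMB8 (20.6%) and RRM2 (20.2%), and their values are less certain for it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.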

Results

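RNA was sequenced from 8 samples of LN229, an established human glioblastoma cell line. In 4 samples the cells had been exposed for 48 h to bortezomib at 7.5 nM, a proteasome inhibitor, together with panobinostat at 15 nM, an inhibitor of histone deacetylases (HDACs). The other 4 samples received DMSO, the solvent. The comparison addresses how the transcriptome of these cells changes under the drug pair, which is called the combination here. Each library held between 15189251 and 17324292 reads assigned to genes. The mean number was 1.02 times as high after the combination, a difference within the spread between samples (exact permutation test, n = 4 each, two-sided p = 0.571). Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are fragments scaled by gene length and library size (FPKM), given as mean ± SD over 4 samples, with the combination first and DMSO second. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over all genes tested.

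After the combination, all 26 tested genes of mitosis, 25 of 26 of DNA replication, all 17 of recombination repair and all 22 of the interferon response were lower. Higher were 27 of 32 proteasome subunit genes, 15 of 22 autophagy and lysosome genes and 14 of 19 antioxidant genes. So were 27 of 30 cytosolic ribosomal protein genes and 12 of 15 glycolysis genes. As lists, these passed with a preset correlation but not with an estimated correlation (adjusted p = 0.088 for repair, adjusted p = 0.178 for mitosis, replication and autophagy, adjusted p = 0.371 for ribosomal proteins, adjusted p = 0.316 for the others). Of 13296 genes tested, 4902 were higher (36.9%) and 5445 were lower (41.0%). The balance depended on the settings, since higher genes outnumbered lower ones without the filter on low values (7747 against 6386) and with upper-quartile (5549 against 4886), nuclear read (5450 against 5180) and quantile scaling (5496 against 4938). A change of at least 2-fold was found for 1176 higher and 1475 lower genes, for 428 and 672 with a pseudocount of 5, for 1656 and 1988 with voom, and for 1351 and 1331 with upper-quartile factors. The first principal component held 90.1% of the variance and separated the groups. Correlations of log2 values within a group were at least 0.986, and between groups at most 0.823.

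Of the 8 largest increases, 5 belonged to genes with at most 11 reads in any DMSO sample. KRTAP2-3, a hair keratin-associated protein gene on chromosome 17 (41059240 to 41060114, GRCh38), went from 0.0843 ± 0.0822 to 141 ± 9.86 FPKM, with 0 to 3 reads in each DMSO sample. CPA4, a metallocarboxypeptidase on chromosome 7 (130293134 to 130324180), stood at 286 ± 12.6 against 1.94 ± 0.373 FPKM, a log2 fold change of 6.62 ± 0.0820 (SE, adjusted p = 2.65e-11). BEX1 reached 83.2 ± 6.17 against 0.332 ± 0.301 FPKM, and CLU, the secreted chaperone clusterin, 251 ± 12.9 against 5.08 ± 0.413 FPKM. The cancer-testis gene SPANXB1 stood at 61.4 ± 3.84 against 0.130 ± 0.00570 FPKM, and the long non-coding gene AL161431.1 at 139 ± 5.13 against 2.24 ± 0.199 FPKM. IGFL2-AS1 (125 ± 8.0 FPKM) and IGFL1P1 (73.8 ± 1.86 FPKM) lie on opposite strands of the same stretch of chromosome 19, with no overlapping exons. Reads of KRTAP2-3 and SPANXB1 can be shared with near-identical family members.

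The largest decreases fell on interferon-induced genes and on genes of mitosis. IFITM1, which restricts virus entry, dropped from 117 ± 28.6 to 0.0742 ± 0.0748 FPKM, and its neighbour IFITM3 from 276 ± 38.1 to 5.57 ± 0.945 FPKM. Their sequences are similar enough for reads to be shared, and 32.5% of the exon length of IFITM1 lies under exons of other genes on the same strand. The ubiquitin-like modifier ISG15 stood at 10.7 ± 1.67 against 344 ± 61.9 FPKM, a log2 fold change of -4.88 ± 0.139 (SE, adjusted p = 1.56e-09). KIF20A, a mitotic kinesin, had 1.45 ± 0.297 against 67.7 ± 5.29 FPKM, and UBE2C, which serves the anaphase-promoting complex, 6.03 ± 0.875 against 149 ± 8.33 FPKM. CAPS, which encodes a calcium-binding protein, stood at 3.02 ± 0.203 against 91.7 ± 4.05 FPKM.

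**Figure D1:**
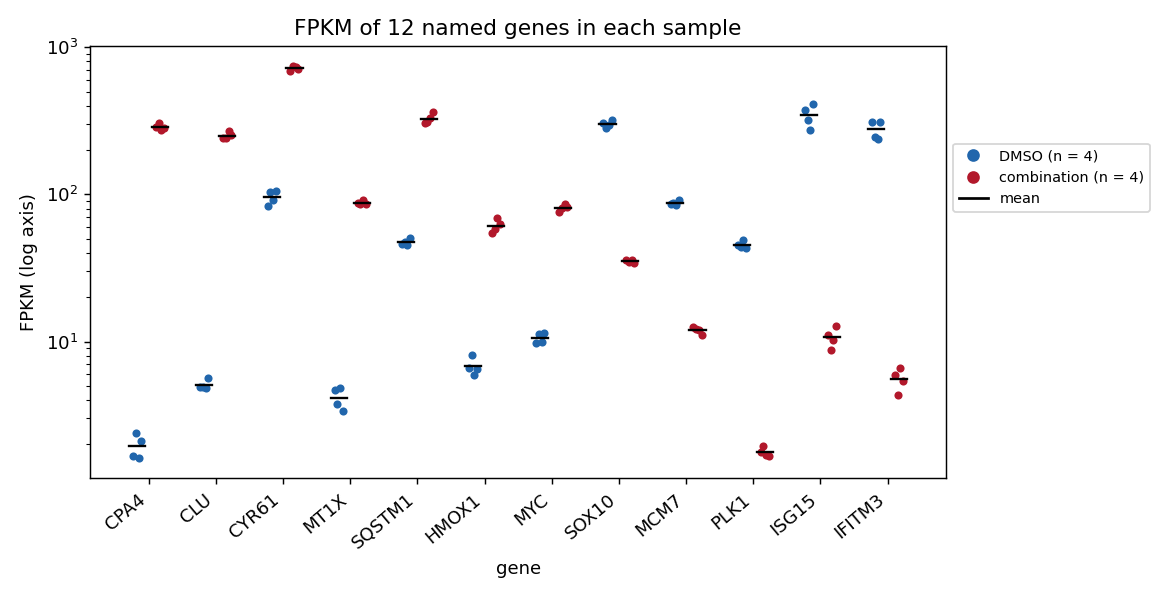
FPKM on a log axis of 12 named genes in each of the 4 DMSO samples (blue) and the 4 samples given the combination (red), with black bars for group means. The groups do not overlap in any of these genes, from CPA4 (286 against 1.94 FPKM) to IFITM3 (5.57 against 276 FPKM).

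Genes of cell division fell as a block. All 26 tested genes of G2/M and mitosis were lower, with a median log2 fold change of -3.80. PLK1, a mitotic kinase, stood at 1.76 ± 0.126 against 45.2 ± 2.44 FPKM, and AURKB, another one, at 1.14 ± 0.0692 against 30.3 ± 1.21 FPKM. Of 26 genes of G1/S and DNA replication, 25 were lower (median -2.34), among them the replicative helicase subunit MCM7 (11.9 ± 0.609 against 87.6 ± 3.36 FPKM) and the ribonucleotide reductase subunit RRM2 (1.90 ± 0.201 against 33.7 ± 1.67 FPKM). All 17 tested genes of homologous recombination and Fanconi repair were lower too (median -1.95). FANCI stood at 1.23 ± 0.150 against 15.5 ± 0.283 FPKM, RAD54L at 0.418 ± 0.0949 against 8.72 ± 0.290 FPKM, and BRCA1 at 0.285 ± 0.0520 against 3.98 ± 0.136 FPKM. The camera test of limma, with a preset correlation, placed these lists below other genes with adjusted p = 2.36e-12, 1.92e-10 and 5.11e-07 in the order given. With an estimated correlation the adjusted p-values were 0.178, 0.178 and 0.088.

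Type I interferon response genes fell without exception among the 22 that could be tested, with a median log2 fold change of -3.57. OAS3, which makes the activator of RNase L, stood at 1.11 ± 0.0358 against 56.9 ± 7.55 FPKM, and IFIT3 at 1.75 ± 0.348 against 73.1 ± 12.4 FPKM. The list had adjusted p = 1.76e-08 with the preset and adjusted p = 0.316 with an estimated correlation. In class I antigen presentation, 12 of 14 genes were lower and 1 was higher (adjusted p = 0.00225 preset, adjusted p = 0.451 with an estimated correlation). The immunoproteasome subunit PSMB8 stood at 5.47 ± 0.237 against 27.6 ± 3.20 FPKM and the peptide-trimming enzyme ERAP1 at 2.57 ± 0.10 against 8.83 ± 0.391 FPKM.

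Proteasome subunit genes rose modestly and together. Of 32 tested, 27 were higher and 2 lower (PSMC3, and PSMA7, whose call was lost with upper-quartile factors), with a median log2 fold change of 0.54 (adjusted p = 5.11e-07 preset, adjusted p = 0.316 with an estimated correlation). PSMD13 stood at 54.6 ± 2.90 against 23.1 ± 0.430 FPKM and PSMB1 at 84.1 ± 3.34 against 40.5 ± 1.46 FPKM. PSMB5, the subunit that bortezomib binds, stood at 90.8 ± 5.96 against 67.2 ± 1.44 FPKM. Transcripts of NFE2L1, a transcription factor of proteasome genes, stood at 48.0 ± 1.16 against 53.3 ± 2.80 FPKM, a decrease whose call was lost with upper-quartile factors. Among 20 ubiquitin genes and shuttle factors 13 were higher and 1 lower (UCHL5), with adjusted p = 0.00319 preset and adjusted p = 0.262 with an estimated correlation. SQSTM1, an autophagy receptor for ubiquitinated cargo, rose most clearly, to 327 ± 25.5 from 47.5 ± 2.35 FPKM. Autophagy and lysosome genes, a list that also holds SQSTM1, were higher in 15 and lower in 2 of 22 cases (adjusted p = 0.000407 preset, adjusted p = 0.178 with an estimated correlation). The lysosomal protease CTSB stood at 204 ± 3.56 against 65.9 ± 1.04 FPKM.

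Antioxidant genes controlled by NRF2 were higher in 14 and lower in 4 of 19 cases (median 1.02, adjusted p = 0.000695 preset, adjusted p = 0.316 with an estimated correlation). HMOX1, which degrades heme, rose to 61.4 ± 6.35 from 6.80 ± 0.942 FPKM, and the aldose reductase gene AKR1B1 to 401 ± 22.1 from 57.3 ± 1.48 FPKM. OSGIN1 stood at 58.8 ± 3.82 against 15.5 ± 0.546 FPKM. NQO1, a quinone reductase in the same list, fell to 88.8 ± 5.86 from 430 ± 7.53 FPKM, with a log2 fold change of -2.27 ± 0.0474 (SE, adjusted p = 2.33e-10). Transcripts of NRF2 itself (NFE2L2) stood at 18.9 ± 0.265 against 21 ± 0.541 FPKM, lower in this test but not with upper-quartile factors or quantile normalization. All 3 tested metallothioneins were higher (adjusted p = 0.0108 preset, adjusted p = 0.178 with an estimated correlation, adjusted p = 0.0615 with quantile normalization). MT1X reached 87.7 ± 2.54 against 4.16 ± 0.683 FPKM and MT1E 116 ± 3.84 against 26.9 ± 1.2 FPKM, though reads of this family can be shared between members.

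Chaperone genes did not follow the proteasome genes. Of 21 genes of endoplasmic reticulum chaperones and degradation, 17 were lower and 4 higher (median -0.71, adjusted p = 0.000695 preset, adjusted p = 0.316 with an estimated correlation). HYOU1 stood at 17.4 ± 0.925 against 62.3 ± 1.36 FPKM and MANF at 45.8 ± 2.24 against 142 ± 3.78 FPKM, whereas DNAJB9 was higher (8.0 ± 0.418 against 4.49 ± 0.457 FPKM). Cytosolic heat shock genes went both ways, with 6 higher and 15 lower of 24, and the list did not pass (adjusted p = 0.140). The small heat shock gene HSPB8 rose to 26.2 ± 1.63 from 11 ± 0.40 FPKM and the co-chaperone BAG3 to 40.6 ± 0.954 from 29.1 ± 1.48 FPKM. HSPA8, the constitutive HSP70 gene, fell to 77.2 ± 3.18 from 274 ± 7.67 FPKM, and SERPINH1, a collagen chaperone of the endoplasmic reticulum that the list also holds, to 7.70 ± 0.438 from 126 ± 1.45 FPKM. The inducible genes HSPA1A (log2 fold change -0.35) and HSPA1B (0.64) are near-identical, so their opposite signs are uncertain. HSF1, the transcription factor of the heat shock response, stood at 20.6 ± 0.991 against 19.8 ± 1.42 FPKM (adjusted p = 0.399).

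Genes of the integrated stress response under ATF4 were split, with 8 higher and 10 lower of 19 (adjusted p = 0.709). ATF3 stood at 25.5 ± 1.5 against 10.04 ± 1.0 FPKM and STC2 at 15.7 ± 0.154 against 4.82 ± 0.389 FPKM, while ATF5 fell to 1.6 ± 0.0562 from 8.89 ± 0.591 FPKM. DDIT3 was higher (29.8 ± 1.91 against 22.2 ± 0.708 FPKM), with 39.6% of its exon length under exons of other genes, and TRIB3 stood at 10.2 ± 0.362 against 11 ± 0.926 FPKM (adjusted p = 0.141). Of 17 targets of p53, 5 were higher and 11 lower (adjusted p = 0.180). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, stood at 70.4 ± 4.66 against 47.6 ± 2.92 FPKM, GADD45A at 91.8 ± 5.70 against 51.3 ± 2.45 FPKM, and the repair gene DDB2 at 5.44 ± 0.307 against 24.1 ± 0.261 FPKM.

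Neither apoptosis list passed. Pro-apoptotic genes numbered 5 higher and 9 lower of 16 (adjusted p = 0.575), and anti-apoptotic genes 2 higher and 8 lower of 10 (adjusted p = 0.141). Among the BH3-only genes, PMAIP1 (NOXA) stood at 70.0 ± 2.12 against 47.2 ± 4.10 FPKM, BBC3 (PUMA) at 4.08 ± 0.689 against 1.91 ± 0.298 FPKM, BMF at 3.46 ± 0.433 against 1.33 ± 0.121 FPKM, and BCL2L11 (BIM) at 2.20 ± 0.258 against 1.93 ± 0.240 FPKM (adjusted p = 0.178). The survival gene BCL2L1 rose to 37.9 ± 1.47 from 12.7 ± 0.75 FPKM, with 43.0% of its exon length under antisense exons. MCL1 was lower (137 ± 7.81 against 166 ± 18 FPKM), and BIRC5, whose product survivin also serves mitosis, fell to 3.06 ± 0.50 from 82.7 ± 2.13 FPKM.

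Of 14 histone deacetylase and sirtuin genes 6 were higher and 4 lower, none by 2-fold (adjusted p = 0.432). Panobinostat acts on the classical deacetylases and not on sirtuins. HDAC3 stood at 29.4 ± 1.43 against 17.2 ± 0.222 FPKM, HDAC1 at 37.4 ± 1.46 against 39.4 ± 1.09 FPKM (adjusted p = 0.0988) and HDAC6 at 3.23 ± 0.262 against 4.19 ± 0.0937 FPKM. H1F0, a linker histone gene long known to respond to HDAC inhibitors, stood at 343 ± 24.3 against 245 ± 23.2 FPKM. TXNIP, the thioredoxin-interacting protein gene, rose to 95.4 ± 2.51 from 21.1 ± 1.73 FPKM. Of 10 replication-dependent histone genes 7 were higher and 2 lower (adjusted p = 0.0499 preset, adjusted p = 0.212 with an estimated correlation). HIST1H1C stood at 157 ± 20.2 against 22.9 ± 2.09 FPKM and HIST1H2BD at 39.6 ± 4.04 against 7.19 ± 0.408 FPKM, and reads of histone genes can be shared between copies.

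MYC rose to 81.3 ± 3.78 from 10.6 ± 0.890 FPKM and MET, the hepatocyte growth factor receptor, to 58.4 ± 2.34 from 12.7 ± 0.352 FPKM. ERBB2 fell to 2.11 ± 0.145 from 15.2 ± 0.828 FPKM and AXL to 27.7 ± 0.748 from 88.6 ± 3.56 FPKM. Their list of receptor tyrosine kinase and growth genes had 5 higher and 14 lower of 22 (adjusted p = 0.0499 preset, adjusted p = 0.212 with an estimated correlation). In the list of NF-kB targets and cytokines, 9 were higher and 6 lower of 17 (adjusted p = 0.505). The neutrophil chemokine CXCL8 rose to 233 ± 12 from 22.4 ± 4.08 FPKM and IL6 to 4.63 ± 0.367 from 0.669 ± 0.0416 FPKM, whereas LIF fell to 12.3 ± 0.786 from 78.5 ± 4.52 FPKM and NFKB1 to 3.0 ± 0.183 from 12.6 ± 0.567 FPKM. Counts adjusted over the list alone equalled those given for every list except this one, where 7 in place of 6 were lower.

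Ribosomal protein and glycolysis genes rose about as much as proteasome subunit genes (median 0.54), while the other metabolic lists moved less. Of 30 cytosolic ribosomal protein genes 27 were higher and 1 lower (median 0.56, adjusted p = 5.11e-07 preset, adjusted p = 0.371 with an estimated correlation), such as RPL23 (121 ± 5.53 against 59.2 ± 1.26 FPKM). Glycolysis genes were higher in 12 and lower in 1 of 15 cases (median 0.61, adjusted p = 0.000695 preset, adjusted p = 0.316 with an estimated correlation), with PGK1 at 261 ± 8.47 against 124 ± 3.08 FPKM and PKM at 914 ± 34.4 against 470 ± 2.29 FPKM. Nuclear genes of oxidative phosphorylation were higher in 13 and lower in 2 of 23 cases, with a median of 0.12 (adjusted p = 0.0499 preset, adjusted p = 0.476 with an estimated correlation). With library totals 10 were higher and 5 lower (median 0.06), and with upper-quartile factors 15 and 2 (median 0.22). NDUFA4 stood at 102 ± 5.40 against 54.4 ± 2.35 FPKM and ATP5F1B at 219 ± 7.12 against 282 ± 5.25 FPKM. Cholesterol synthesis genes went both ways, with 7 higher and 10 lower of 20 (adjusted p = 0.516), with DHCR7 at 32.5 ± 1.2 against 22.1 ± 0.933 FPKM.

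The share of reads from mitochondrial genes was 13.6% ± 1.62 after the combination and 5.47% ± 0.975 in DMSO, a ratio of 2.48 with no overlap of the groups (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 can give). Of 37 mitochondrial genes tested 20 were higher and 5 lower, and all 13 protein genes among them were higher, by log2 fold changes of 0.88 to 1.68. The ferritin genes FTL and FTH1 together took 1.11% ± 0.0532 of reads against 0.278% ± 0.0171, with the same exact p. Their reads can be shared with ferritin pseudogenes. Genes with at least 1 read numbered 28506 ± 583 against 25373 ± 332, again without overlap and with the same exact p. These differences of the libraries accompany every gene group above.

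**Figure D2:**
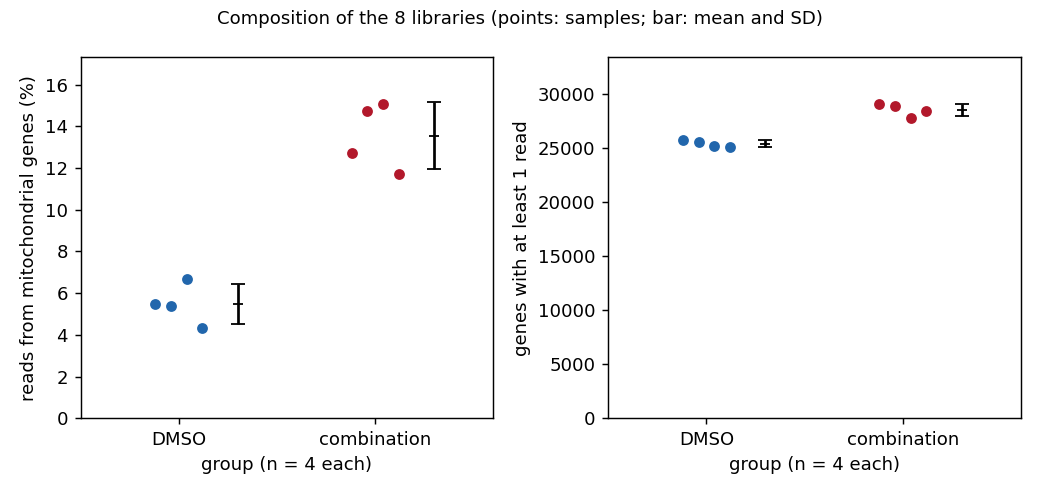
Percent of reads from mitochondrial genes (left) and number of genes with at least 1 read (right) in each sample, with the group mean and SD (n = 4 each) as a black bar beside the points. Both measures are higher in all 4 samples given the combination, at 13.6% against 5.47% and 28506 against 25373 genes on average.

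Markers of neural lineages moved in opposite directions. Of 14 tested neuron markers 11 were higher and 3 lower (median 1.18, adjusted p = 0.00211 preset, adjusted p = 0.178 with an estimated correlation). SYP, the synaptic vesicle protein synaptophysin, stood at 17 ± 1.06 against 0.245 ± 0.0567 FPKM and UCHL1, a deubiquitinase abundant in neurons, at 342 ± 17.4 against 62.6 ± 1.70 FPKM. All 5 tested oligodendrocyte markers were lower (median -2.74, adjusted p = 0.00211 preset, adjusted p = 0.178 with an estimated correlation). SOX10, a transcription factor of glia and neural crest on chromosome 22 (37970686 to 37987422, GRCh38), fell to 35.2 ± 0.837 from 301 ± 14.9 FPKM. Astrocyte markers were split, 3 higher and 2 lower of 5 (adjusted p = 0.379), with GJA1 at 22 ± 0.393 against 7.32 ± 0.249 FPKM and S100B at 17.8 ± 0.823 against 257 ± 6.59 FPKM. Proneural and neural stem cell genes numbered 3 higher and 6 lower of 9 (adjusted p = 0.179). NES (nestin) stood at 58.6 ± 1.1 against 188 ± 5.29 FPKM and ERBB3 at 5.38 ± 0.374 against 47.7 ± 1.2 FPKM. Among the higher ones, NCAM1 stood at 7.19 ± 0.221 against 3.32 ± 0.155 FPKM and BCAN at 2.44 ± 0.384 against 0.354 ± 0.0334 FPKM.

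Mesenchymal and matrix genes were also divided, with 12 higher and 9 lower of 23 (adjusted p = 0.594). CYR61, which encodes a matrix-associated protein, rose to 719 ± 28.3 from 95.9 ± 10.6 FPKM, whereas SPARC fell to 145 ± 3.94 from 518 ± 3.25 FPKM and the gelatinase MMP2 to 98.6 ± 2.15 from 416 ± 19.5 FPKM. The median of this list was 0.24 (0.15 with quantile normalization) and its mean 0.12, while the fry test of limma gave the direction down. Fibroblast markers were higher in 3 and lower in 1 of 4 cases (adjusted p = 0.161, and adjusted p = 0.0290 to 0.0364 when any 1 DMSO sample was left out), among them LUM at 42.9 ± 1.54 against 10.2 ± 0.923 FPKM. All 3 tested epithelial markers were higher (adjusted p = 0.0499 preset, adjusted p = 0.266 with an estimated correlation), with CLDN4 at 3.69 ± 0.207 against 0.561 ± 0.0629 FPKM. None of the markers of endothelium (10), immune cells (12) or muscle (10) reached a mean of 1 FPKM.

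**Figure D3:**
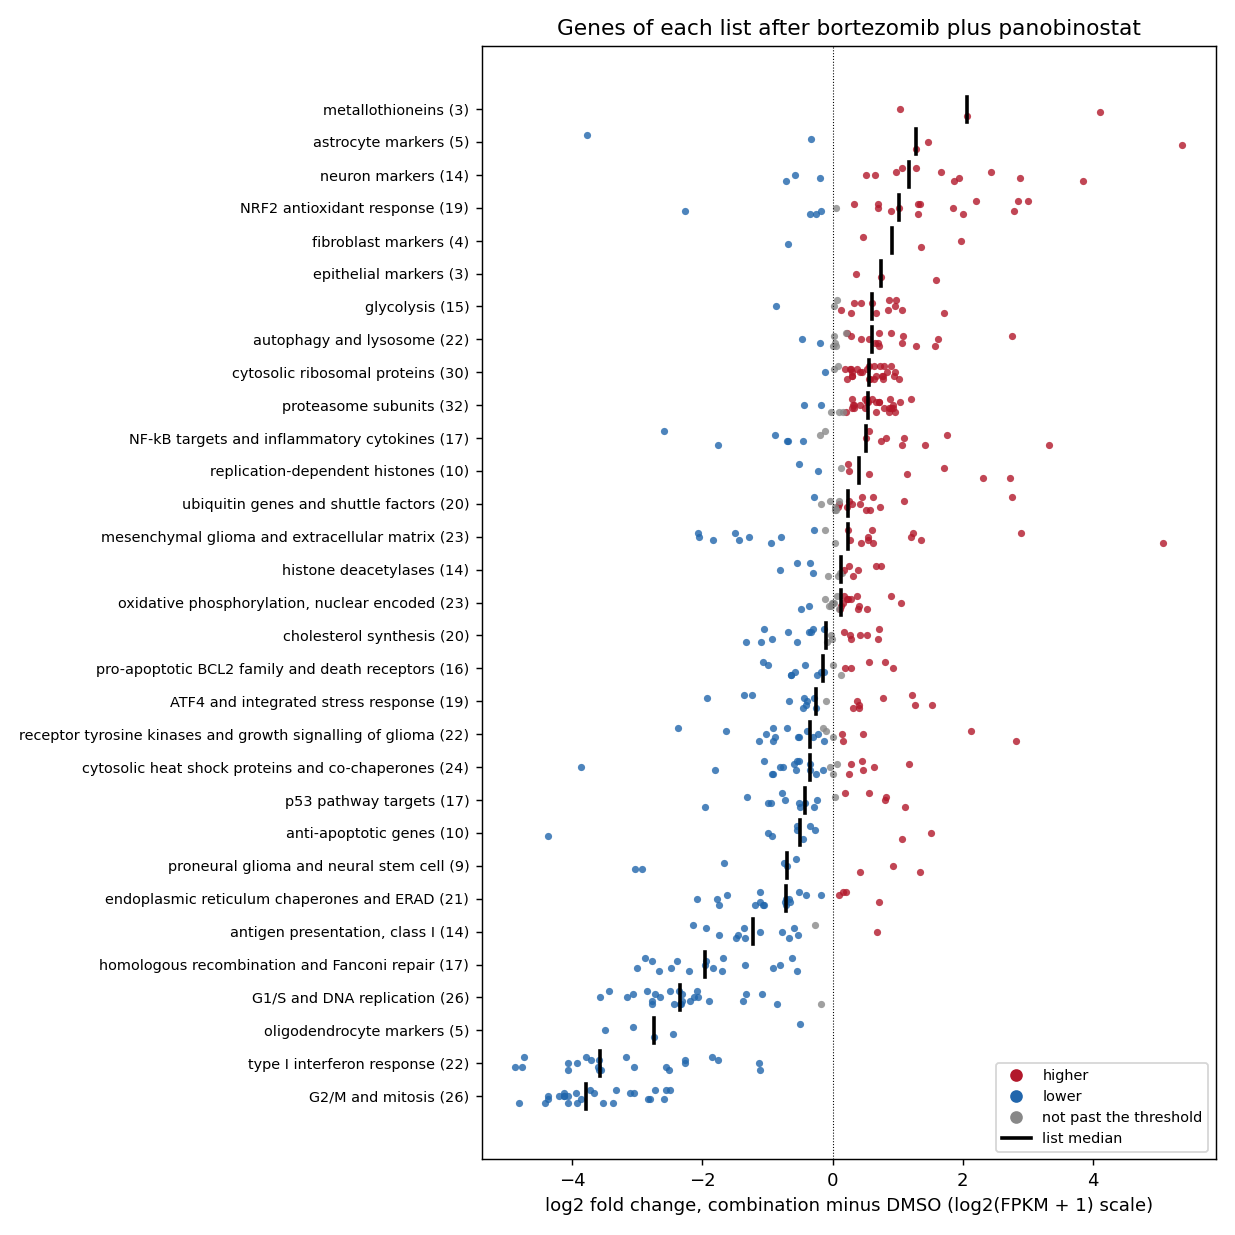
Log2 fold change (combination minus DMSO) on the log2(FPKM + 1) scale of each tested gene, by list, with the number of tested genes in brackets and a black bar for the list median. Red genes were higher, blue genes lower and grey genes not past the threshold. The medians run from 2.06 for metallothioneins to -3.80 for G2/M and mitosis.

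Among genes often used as references, GAPDH stood at 1637 ± 50.6 against 1604 ± 34.5 FPKM (adjusted p = 0.553) and TBP at 6.24 ± 0.385 against 6.02 ± 0.259 FPKM (adjusted p = 0.422). ACTB was lower (886 ± 38.8 against 1308 ± 39.2 FPKM), as was PPIA (254 ± 8.42 against 390 ± 17.4 FPKM). With quantile normalization GAPDH was lower by a log2 fold change of -0.76 (adjusted p = 1.22e-08). No list passed the threshold with an estimated correlation, and the lists at an adjusted p of 0.0499 also lost their calls when single samples were left out.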

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

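Of the tests in this part, the within-library ratio of mitochondrial reads and the share of gained genes near an expressed gene were chosen only after the result was seen. So were the requirement that nuclear-retained RNAs all move one way and the count of splits by their balance.

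Mitochondrial genes took 2.48 times the share of reads after the combination, counted within each library, so scaling between libraries cannot have made the difference. Weaker selection against RNA without a poly(A) tail is not settled. The share of small non-coding RNA genes rose by 0.25 on the log2 scale (SE 0.0744) where the mitochondrial share rose by 1.32. This goes against weaker selection, but these genes held on average only 720 reads per combination library and 648 per DMSO library. Other values go with weaker selection in part. MALAT1 and NEAT1 rose by at least as much as the mitochondrial share. Of 10 replication-dependent histone genes 7 were higher and 2 lower (median 0.41), while genes of DNA replication fell (median -2.34). Loss of cytoplasmic RNA from damaged cells stays open: of 3 nuclear-retained RNAs, MALAT1 (log2 fold change 1.45) and NEAT1 (2.12) rose while TUG1 fell (-0.51), a median of 1.45, and they are too few and too divided to decide. A change of mitochondrial transcript levels under the drugs is a candidate explanation and was not tested apart from these.

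More genes had at least 1 read after the combination, and with nuclear reads thinned to the number in the smallest library the difference was 3351 genes (28278 ± 609 against 24927 ± 283, n = 4 each, no overlap), so depth is argued against. Genomic DNA is argued against as the source of most reads that silent genes gained. Among genes silent in DMSO (at most 2 reads over the 4 samples), 365 were olfactory receptor genes and 31703 were others. The former gained 0.139 times as many reads per kilobase as the latter (0.127 to 0.150 over the 4 libraries). That ratio weighs reads and not genes, so strongly induced genes lower it. It cannot decide whether a thin DNA background added genes with few reads. The 635 gained genes examined next had at least 3 reads in every combination sample, so genes that gained fewer reads were left out. Genes with a DMSO mean of at least 5 FPKM were taken as expressed. Read-through over at most 10 kb from such genes is argued against as the source of most of these 635 genes. Of the 635, 2.05% started that close downstream of such a gene. A contribution to these few stays open, since that share was 1.17 times the share among genes that stayed silent (interval 0.547 to 1.84). Longer read-through was not tested, nor was read-through from genes that reached this level only after the combination. Opening of silent chromatin under an HDAC inhibitor may also contribute and was not tested.

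Among 45439 genes under the expression filter, 299 had at least 3 reads in every sample given the combination and no read in DMSO, and 19 showed the reverse. By total reads the first were HES2 (406), UCA1 (403), TRIM29 (283) and SNCB (224), chosen after their values were seen.

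In 16 of 292 groups of 4 values, 1 sample lay apart from the other 3 by a gap close to the whole range of the group, where chance gives about 14.6. In DMSO these were IGFL2-AS1 in replicate 3 (0 FPKM), IGFL1P1 in replicate 1 (0.479), CLU in replicate 4 (5.69), RRM2 in replicate 2 (36.2), RAD54L in replicate 2 (9.15), HIST1H2BC in replicate 4 (3.19), BCL2L2 in replicate 2 (12.8) and SYP in replicate 3 (0.161). After the combination they were BAG3 in replicate 3 (42.1 FPKM), HERPUD1 in replicate 1 (21.6), MCOLN1 in replicate 2 (4.75), MMP2 in replicate 2 (95.4), SYP in replicate 4 (18.6), LUM in replicate 4 (40.6), CDKN1A in replicate 4 (77.3) and BBC3 in replicate 3 (5.11).

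The 8 samples can be split into 4 and 4 in 35 ways. The real split alone, 1 of 35, gave 10347 genes past the threshold, and the highest of the others gave 1. For genes past it by at least 2-fold the real split gave 2651 and the highest other 1, again 1 of 35 as large. All other splits mix the treatments, so the treatment difference adds to their spread and makes low counts likely. A share of 1 of 35 is also the smallest these splits can give, so both counts say little on chance. With camera at the preset correlation the real split called 19 lists, which 1 of 35 splits reached, and the highest other called 16. The 16 splits that put 3 samples of one treatment with 1 of the other keep part of the treatment difference, and all 16 called at least 1 list. Of the 18 splits with 2 samples of each treatment on both sides, 5 called a list, and none more than 2.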

How the results depend on the processing

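Chosen after seeing the data were voom, scaling by nuclear reads, and upper-quartile, TMM and quantile scaling for the lists. The planned tests that need deposited counts were not run, since the table holds FPKM. Scaling moved the higher genes between 4445 and 5549 and the lower ones between 4886 and 5904. Higher genes made up 47.4% of calls, and 43.0% to 54.8% over all alternatives. Without a low-value filter 7747 genes were higher and 6386 lower, so that higher genes were the majority, as with upper-quartile, nuclear read and quantile scaling. A pseudocount of 0.1 gave 1621 higher and 1928 lower genes by at least 2-fold, and voom 1656 and 1988. With a filter at 5 FPKM, which tests 7258 genes, 2821 were higher and 3277 lower, 584 and 920 of them by at least 2-fold. A pseudocount of 5, which shrinks changes of low genes, left 428 and 672 by at least 2-fold. Leaving out each sample gave 4640 to 4875 higher and 5255 to 5408 lower genes. Depth limits what genes below about 0.197 FPKM can show.

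Of 2799 values of 141 named genes under the alternatives, 2757 kept direction and side of the threshold, 25 lost the call, 10 gained it and 7 changed sign. The last were, with library totals, HSF1 (-0.0151), GAPDH (-0.0409) and TBP (-0.0159), with upper-quartile factors HDAC1 (0.0205), with TMM factors GAPDH (-0.00113), and with quantile normalization TRIB3 (0.0199) and GAPDH (-0.755). Only the last was called, and its cause was not tested. The lost calls were of PSMA7, HIST1H2AC, MCOLN1, RPS2, NFE2L1 and NFE2L2.

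Between 15 and 20 lists passed with another scaling, the stricter filter, the replicate block or a sample left out. Lists that lost the call had these adjusted p-values, and the cause was not tested. With library totals they were 0.121 for oxidative phosphorylation and 0.0617 for growth signalling. With median-of-ratios factors the value was 0.05 for histones, growth signalling and epithelial markers alike. With upper-quartile factors these 3 had 0.0632, 0.0584 and 0.0677, and with nuclear reads 0.0549 each. With TMM factors oxidative phosphorylation had 0.0697 and growth signalling 0.0524. With quantile normalization metallothioneins, histones and epithelial markers had 0.0615 and growth signalling 0.0797. At 5 FPKM histones had 0.118, oxidative phosphorylation 0.0578 and growth signalling 0.0770, while epithelial and fibroblast markers kept too few genes to be tested.

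Leaving out single samples gave 0.0417 to 0.0539 for histones (lost without combination replicate 4 at 0.0510, DMSO replicate 2 at 0.0505 or 3 at 0.0539). For oxidative phosphorylation the range was 0.0309 to 0.0609 (lost without combination replicate 3 at 0.0580 or 4 at 0.0510, DMSO replicate 2 at 0.0528, 3 at 0.0573 or 4 at 0.0609). For growth signalling it was 0.0456 to 0.0634 (lost without combination replicate 1 at 0.0596, 2 at 0.0554, 3 at 0.0634 or 4 at 0.0565, or DMSO replicate 3 at 0.0539). For epithelial markers it was 0.0451 to 0.0599 (lost without combination replicate 1 at 0.0505 or 4 at 0.0513, DMSO replicate 2 at 0.0544, 3 at 0.0539 or 4 at 0.0599). Fibroblast markers ranged from 0.0290 to 0.172 and passed without DMSO replicate 1 (0.0361), 2 (0.0290), 3 (0.0364) or 4 (0.0325). In each of these fits FAP, the only lower member, fell under the filter on low values. The list that passed thus held higher genes alone and was not the list of the main test.

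Replicate numbers did not pair the samples: deviations of samples with the same number correlated at 0.00203, 0.0503, -0.0234 and 0.0672, and 1 of 4 combination samples correlated best with its own number. With the replicate number as a block 4839 genes were higher and 5404 lower, and histones (0.0504), oxidative phosphorylation (0.0522), growth signalling (0.0583) and epithelial markers (0.0552) missed the threshold.

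With an estimated correlation 0 of 31 lists passed. The values were 0.088 for homologous recombination, 0.178 for metallothioneins, G1/S, G2/M, autophagy, neuron and oligodendrocyte markers, 0.212 for histones and growth signalling, 0.262 for ubiquitin genes, 0.266 for epithelial markers, 0.316 for proteasome, endoplasmic reticulum chaperones, NRF2, glycolysis and interferon, 0.371 for ribosomal proteins, 0.451 for class I presentation and 0.476 for oxidative phosphorylation. The estimate lay below the preset 0.01 for metallothioneins (-0.115), histones (-0.00826) and growth signalling (-0.00314), which also missed the threshold. A higher correlation among their own genes was therefore not what cost these lists their calls. The fry test, which does not compare a list with other genes, passed 30 lists. Those it added were heat shock proteins (1.26e-06), ATF4 (0.000391), p53 (1.28e-06), histone deacetylases (0.00144), pro-apoptotic (0.000911) and anti-apoptotic genes (1.38e-06), cholesterol synthesis (8.01e-06), proneural genes (3.18e-09), astrocyte (5.95e-07) and fibroblast markers (3.04e-07), and mesenchymal genes in the opposite direction (6.58e-05).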

Other observations

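Genes and families in this part were chosen after values were seen, as were all comparisons of families and gene types. The SOX10 list was written before its members' values were looked at, but 6 members shared with earlier lists were left out after a first result.

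Other single genes with large increases were TNFSF9, CD70, VGF, SCG2, CALB2, IL11 and IL24, which were not tested together as a group. IL11 and IL24 also count in the IL family by symbol given below. TNFSF9, the ligand of the costimulatory receptor 4-1BB, stood at 505 ± 22.9 FPKM after the combination against 17.5 ± 1.81 FPKM in DMSO (mean ± SD, n = 4 each), and CD70, the ligand of CD27, at 248 ± 12.3 against 35.4 ± 1.12 FPKM. The neuropeptide precursor gene VGF stood at 270 ± 6.67 against 5.93 ± 0.496 FPKM, the granin SCG2 at 65.6 ± 0.836 against 8.59 ± 1.0 FPKM, and the calcium-binding protein gene CALB2 at 58.1 ± 1.19 against 0.455 ± 0.0379 FPKM. The cytokine gene IL11 stood at 146 ± 14.2 against 10.6 ± 0.810 FPKM and IL24 at 21 ± 1.66 against 0.307 ± 0.0135 FPKM. All of these were higher in 4 of 4 samples and passed limma's test.

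Families of genes sharing the start of a symbol were searched for an excess of 2-fold changes (389 families, 778 hypergeometric tests that treat genes as independent, Benjamini-Hochberg adjusted), and 12 passed. Lower were MCM genes (8 of 9, of which MCM8 and MCM10 are no subunits of the replicative helicase, adjusted p = 0.000135), CDCA (6 of 7, 0.00182), CNTNAP (5 of 5, 0.00190), KIF kinesins (12 of 28, 0.00190), IFI (6 of 8, 0.00396), HMGB (5 of 6, 0.00761), COL collagens (10 of 24, 0.00908) and RFC clamp loader genes (4 of 5, 0.0434). Higher were TRBV (5 of 5, 0.000759), FTH (5 of 6, 0.00182), KRT keratins (7 of 13, 0.00182) and IL (7 of 22, 0.0434). Reads of CNTNAP3 copies, FTH1 and HMGB1 pseudogenes and TRBV segments can be shared between near-identical sequences. The COL family by symbol includes COL4A3BP, which is no collagen, and without the 2-fold limit 9 of its members were higher and 14 lower. The IL family by symbol mixes cytokines with receptors (IL1RL1, IL2RB, IL31RA), and without the 2-fold limit 9 of its members were higher and 11 lower.

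Called genes of non-coding types were more often higher than called protein-coding genes. Of calls among lincRNA genes 75.0% were higher (261 higher, 87 lower), among antisense genes 69.9% and among processed pseudogenes 65.2%, against 44.4% of protein-coding genes. Among genes with a mean of 1 to 5 FPKM the shares were 71.5%, 67.8%, 62.8% and 43.6% (Fisher's exact test of lincRNA against protein-coding genes, two-sided p = 3.13e-19, with genes taken as independent). Of protein-coding genes silent in DMSO, here with at most 2 reads over the 4 samples, 8.67% (375 of 4327) had at least 3 reads in every sample given the combination, against 2.19% of silent lincRNA genes and 0.239% of silent processed pseudogenes. These limits count reads and were not scaled by gene length, so differences in length between gene types can enter the shares.

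SOX10, S100B and ERBB3, genes of glial and Schwann cell identity, were all lower, ERBB3 at 5.38 ± 0.374 against 47.7 ± 1.2 FPKM. A hypothesis was that the wider programme of SOX10 fell with it. Of 20 further genes tied to that programme, 14 could be tested and 12 of them were lower (85.7%, against 41.0% of all genes tested, one-sided exact hypergeometric test, p = 0.000781 with genes taken as independent), with a median log2 fold change of -1.57. CDH19 (-3.52) and CSPG4 (-3.33) fell most, while 2 members rose, NGFR by 1.34 among them. A fall of the programme with SOX10 may therefore be present, though nothing here shows that SOX10 drives it.

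CDKN2A and CDKN2B, neighbours on chromosome 9 (21967753 to 21995301 and 22002903 to 22009363, GRCh38), had 0 reads in all 8 samples. A homozygous deletion of this locus is known in LN229.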
